A study of Oryzias latipes with 5 samples.

How the data were processed

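Messenger RNA was measured by sequencing in 5 libraries of medaka cells that express the col10a1:nlGFP reporter, 3 from wild-type siblings and 2 from heterozygous col10a1 mutants, at 10 days post fertilization after incubation at 30 °C. Per the labels' protocols, RNA was isolated with the Direct-zol MicroPrep kit and libraries were made with a SMARTER mRNA-Seq kit. How the cells were sorted is not given in the sources used here. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used, the former an aligner and the latter a read counter. The genome build, annotation release and strand setting are not given in the sources used here, so coordinates are those of the deposited table and reads of overlapping or antisense genes could not be told apart. The deposited table gives, per the file header, FPKM per gene and library (fragments per kilobase of gene length, scaled to library depth by the authors) together with a gene length in base pairs, coordinates, a symbol for 15595 of 25689 genes and a description. The remaining 10094 genes have no symbol. Names and descriptions were taken from this table as they stand, and a reference table for the assembly ASM223467v1 matched 0 of its gene identifiers and was not used.

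FPKM multiplied by gene length came out in whole steps, so read numbers were recovered for 100.0% of values within 0.02 reads. They summed to 24791662, 27994446, 28012092, 25580595 and 27916294 reads for wild-type 1 to 3 and mutant 1 and 2. The denominator implied by the deposited FPKM was 1.04, 1.05, 1.08, 0.980 and 1.23 times these sums, a scaling by the authors whose basis is not given in the sources used here. It makes FPKM of mutant library 2 lower, relative to its reads, than in the other libraries, which was addressed by 2 other scalings. Reads carry no molecular identifiers, so floors and simulated spreads cover reads, not molecules.

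Groups were taken from the genotype in the labels. The design, the lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The unit, FPKM, was the one the design assumed. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, no covariate, Benjamini-Hochberg adjustment), on 13680 genes with at least 1 FPKM in at least 2 libraries. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes with low values. With 3 residual degrees of freedom, limma's prior added 4.456. col10a1 was also compared by an exact two-sided permutation test over 10 splits (scipy 1.17.1, python 3.11.15, numpy 2.4.6, pandas 2.3.3), and plots were drawn with matplotlib 3.10.9. A threshold of 0.05 on the adjusted p was used throughout.

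There were 25 lists of pathways and skeletal cell types and 11 lists of markers of other cell types. Entries were matched to symbols in lower case, also with the suffixes that mark fish gene copies, which brought in unintended genes such as RHOB for rho in the retina list and ninl for nin in the microtubule list. The 35 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, and beside it with camera at an estimated correlation and with fry. Members were also adjusted over the list alone. The rule for named genes took col10a1, then, from genes with a symbol and a mean of at least 2 FPKM in a group, 12 higher and 12 lower, those past the threshold first and otherwise those with the smallest p, and up to 4 members of each list with the smallest p. No gene with a symbol passed the threshold, so all places went by the smallest p. Further list members given as examples, arf5, apoa1b and the genes without a symbol were named after their values were seen. An item that the rule would name is not reported here.

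The procedure was tested on simulated data. Reads were drawn for the real genes from the real means and depths with a wild-type dispersion of 0.0475 in 20 draws, with 200 genes changed, 40 at each fold. The changed genes had a wild-type mean of at least 5 FPKM. With no gene changed, a mean of 2.4 genes was called per draw, and 15 of 20 draws had a false call. With all libraries varying like the wild-type ones, 44.1% of genes at 2-fold, 99.9% at 4-fold and 100% at 8-fold were called, and 8.17% of calls were unchanged genes. With mutant library 2 varying as observed, 0.125%, 12.8% and 62.0% were called, with 7.12% at a fold of 0.25 and 0% at 0.5, and 0 unchanged genes. That spread was taken around the wild-type means, so it also counts any genotype difference in that library.

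Alternative settings fixed in advance were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, no mean-variance trend, array weights, the replicate number as a block, voom on the recovered reads, a threshold of 0.1, an estimated correlation, fry and leaving out each library in turn. Added after seeing the data were voom with quality weights, removal of each library's trend with gene length, a minimum mean of 20 FPKM and the counts of members called within each list alone without mutant library 2. Leaving out a mutant leaves 1 mutant library, which is then assumed to vary like the wild-type ones. Groups of 3 and 2 are too small for a test of outlying libraries and for counts over other splits of the libraries. Mutant library 2 was kept in the reported values, as the design had fixed, and left out only as an alternative.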

Results

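The data describe messenger RNA from cells that express the col10a1:nlGFP reporter in medaka (Oryzias latipes, Cab strain), a small laboratory fish, at 10 days post fertilization. The labels call these cells chondrocytes and osteoblast progenitors, and all fish were homozygous for the reporter. col10a1 encodes the chain of type X collagen, a matrix protein of hypertrophic cartilage that fish osteoblast precursors also make. There were 3 libraries from wild-type siblings and 2 from heterozygous col10a1 mutants, described as biological replicates, and the comparison asks how expression in these cells differed between the genotypes. The deposited values are FPKM for 25689 genes. The reads they imply came to 24791662, 27994446 and 28012092 in wild-type libraries 1 to 3 and to 25580595 and 27916294 in mutant libraries 1 and 2. At these depths 3 reads on a transcript of 1 kb equalled 0.0871 to 0.120 FPKM, a floor that covers counting error only. Wild-type libraries had reads on 20692, 19397 and 19838 genes and mutant library 1 on 21134, whereas mutant library 2 had reads on 12334 genes and none on 13355. Of 5977 genes at 5 FPKM or more in all 4 other libraries, 374 had no read in mutant library 2. In each of the other libraries the matching number was 0. Pearson's r of log2(FPKM + 1) across tested genes, which are not independent replicates, was 0.80 to 0.82 for pairs with mutant library 2 and 0.95 to 0.97 for all other pairs. This sparse library is 1 of only 2 mutant libraries.

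Transcripts of col10a1a were lower in both mutants than in any wild-type library, a pattern that 3556 of 13680 tested genes showed, but the difference did not pass the test. This copy (ENSORLG00000013436, chromosome 22, 8040396 to 8045500, plus strand) stood at 5384, 7272 and 6781 FPKM in wild-type libraries and at 4055 and 4135 FPKM in the mutants, 6479 ± 980 (SD, n = 3) against 4095 ± 56.3 (SD, n = 2). On the log2(FPKM + 1) scale the difference was -0.65 (SE 0.29, 95% interval -1.32 to 0.02), and limma gave an adjusted p of 0.399. A two-sided exact permutation test gave p = 0.1 over the 10 splits, the smallest p that 3 against 2 libraries can reach. The other copy, col10a1b (ENSORLG00000027315, chromosome 24, 21445251 to 21451154, plus strand), stood at 374, 657 and 461 FPKM against 301 and 580, a log2 difference of -0.21 (SE 0.35) with an adjusted p of 0.746 and an exact permutation p of 0.7. Reads that fit both copies could be split between them, and the labels do not say which copy carries the mutation. The values measure total transcript of each copy and do not separate the mutant from the wild-type allele. Over all alternatives the log2 difference of col10a1a ran from -0.79 to -0.54. It passed only without mutant library 1 (-0.64). The sparse library is then the only mutant, so that pass has no spread among mutants behind it.

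**Figure D1:**
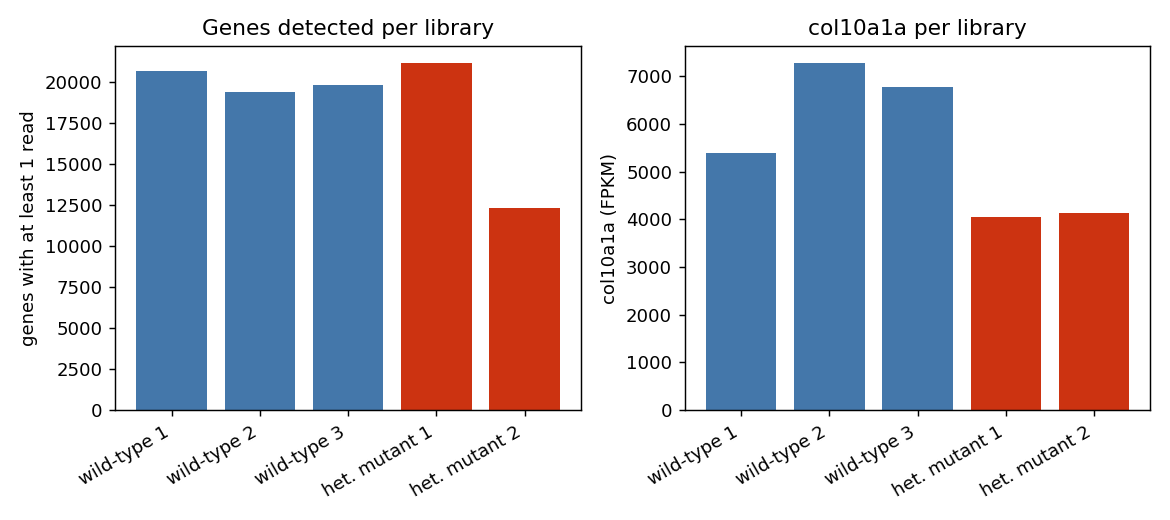
Bars give, for each of the 5 libraries, the number of genes with at least 1 read (left) and the FPKM of col10a1a (right), with wild-type in blue and heterozygous mutants in red. Mutant library 2 has reads on 12334 genes and the others on 19397 or more, while col10a1a lies at 4055 and 4135 FPKM in the mutants and at 5384 or above in the wild-type libraries.

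Among 13680 genes tested, a small GTPase gene described in the deposited table as ADP-ribosylation factor 4 (ENSORLG00000017377, no symbol, chromosome 5, 32570992 to 32573006, plus strand, 546 bp) rose in the mutants and was the only gene to pass at an adjusted p under 0.05. ADP-ribosylation factors recruit vesicle coats at the Golgi. Its level went from 12.2, 4.004 and 11.2 FPKM in wild-type libraries to 3854 and 4379 FPKM in the mutants, 9.12 ± 4.45 (SD, n = 3) against 4116 ± 372 (SD, n = 2). The log2 difference was 8.79 (SE 0.42), with an adjusted p of 0.000912 from limma with Benjamini-Hochberg adjustment. The gene falls outside the rule for named genes, which counts genes without a symbol but does not name them, and it was named after its values were seen. Near copies of this gene could share its reads, and the described relative arf5 stood at 662 ± 74.9 FPKM (SD, n = 3) in wild-type and 1249 ± 253 (SD, n = 2) in mutant libraries, a log2 difference of 0.91 that did not pass. The unadjusted p was under 0.05 for 1479 genes, 439 of them higher in the mutants, where chance alone gives 684. The count lay below chance without wild-type library 2 (376, chance 654), without wild-type library 3 (448, chance 661) and with voom quality weights (584), near it without wild-type library 1 (682, chance 660) and with array weights (738), and reached 8110 without mutant library 1. Without mutant library 2 the ADP-ribosylation factor gene passed together with a gene described as somatoliberin (ENSORLG00000022015), at 18.6 FPKM in mutant library 1 and 0.385, 1.12 and 0.150 in the wild-type libraries. Without mutant library 1, which leaves the sparse library as the only mutant, 7239 genes passed and 5270 of them were lower. The median log2 difference of all tested genes was -0.31 as deposited and 0.01 after quantile normalization, which moved the higher genes to 670 of 1232. Changes of gene groups are therefore read against other genes. Mutants lay above every wild-type library for 1139 genes and below every one for 3556, together 34.3% of the tested genes. Chance gives 20% for both directions together. The excess lay on the lower side only, where the median of all tested genes lay too, so the share is no measure of genotype differences.

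The 12 higher genes with a symbol and the smallest p included sec61b, ssr3, ssr2, pdia6, dnajc3a and manf, which act in the endoplasmic reticulum (ER), but none of the 12 passed the test over all genes (adjusted p 0.292 to 0.399). chac1, a glutathione-degrading enzyme induced under ER and amino acid stress, stood at 71.7 ± 7.30 FPKM (SD, n = 3) in wild-type and 255 ± 25.5 (SD, n = 2) in mutant libraries, a log2 difference of 1.82 (SE 0.21, adjusted p = 0.292, and 0.0490 with voom on the recovered reads, from 9.61e-05 to 0.784 over all alternatives). sec61b, a subunit of the channel through which proteins enter the ER, stood at 69.4 ± 4.16 against 216 ± 49.7 FPKM, and the translocon-associated genes ssr3 and ssr2 differed by 1.60 and 1.12 on the log2 scale. krtcap2, a subunit of the enzyme that attaches N-glycans, differed by 1.15, and zgc:112148, described as a Golgi membrane protein, by 2.40. slc35b1, a nucleotide transporter, stood at 23.7 ± 2.49 against 60.4 ± 3.97 FPKM. fgf23, the phosphate-regulating hormone of bone, was at 0.68, 0.47 and 3.92 FPKM in wild-type libraries and at 21.5 and 42.0 in the mutants, a log2 difference of 3.76 (SE 0.62). ins, encoding insulin, was at 0.350 ± 0.0304 against 10.0 ± 0.325 FPKM, from 25 reads in all wild-type and 502 in all mutant libraries, with a log2 difference of 3.03 (SE 0.41).

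The lower genes with the smallest p included several of cartilage and connective tissue matrix, again with no adjusted p below 0.399. matn1, a cartilage matrix protein, stood at 124 ± 26.5 FPKM (SD, n = 3) in wild-type and 38.8 ± 7.22 (SD, n = 2) in mutant libraries, a log2 difference of -1.64 (SE 0.27). cilp, a protein of the intermediate layer of cartilage, stood at 42.7 ± 1.12 against 19.1 ± 3.94 FPKM, and aspn, a small leucine-rich proteoglycan, at 108 ± 19.5 against 50.9 ± 9.26. paplna, described as papilin, differed by -2.05, col9a2, a chain of type IX collagen, by -1.39, and FGFRL1, a receptor-like binder of fibroblast growth factors, by -1.52. Outside the matrix, angptl4, an inhibitor of lipoprotein lipase, differed by -1.57, aoc2, described as a primary amine oxidase, by -1.61, and seta, described as protein SET, by -1.17. aimp1b, a component of the tRNA synthetase complex, differed by -1.01, zfp36l2, an mRNA decay activator, by -0.88, and si:ch211-251b21.1, described as a glutamate receptor, by -0.92. In a simulation with the spread seen in mutant library 2, 7.12% of genes lowered to 0.25 of their level and 0% of genes lowered to 0.5 were called, against 99.9% and 44.1% when every library varied like the wild-type ones. The genes lowered had a wild-type mean of at least 5 FPKM. The spread also counted any genotype difference in that library.

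Genes of ER chaperones and the unfolded protein response were higher relative to other genes in the mutants. Of 30 measured members 20 were higher and 10 lower, with a median log2 difference of 0.29, and camera with the preset correlation gave an upward adjusted p of 5.46e-07. With an estimated correlation the p was 0.0314 and the adjusted p 0.833, so that call was lost. Of 35 lists tested 8 passed with the preset correlation, 12 without mutant library 2 and 4 without mutant library 1, and none held with an estimated correlation or by fry, which asks whether a list's own genes move on balance (lowest adjusted p = 0.0747). Adjusted over the list alone, 8 genes rose and 0 fell, and over all genes none of the 30 passed. Besides chac1, these were manf, a secreted factor of the stressed ER, at 27.0 ± 1.82 FPKM (SD, n = 3) against 96.4 ± 39.1 (SD, n = 2), the disulfide isomerase pdia6 at 35.8 ± 3.95 against 94.2 ± 15.5, the ER co-chaperone dnajc3a at 37.3 ± 3.71 against 84.0 ± 9.56, and creld2 at 6.22 ± 1.35 against 20.4 ± 2.35. The others were the co-chaperone dnajb9b, the degradation factor derl2, with log2 differences of 1.09 and 0.92, and a gene named ddit3, which the deposited table describes as a methionine tRNA ligase, at 0.574 ± 0.0178 against 4.27 ± 2.55 FPKM. Other members differed less or lay lower. xbp1, a transcription factor of the response, differed by 0.37, herpud1, a factor of ER degradation, by 0.24, the chaperone hsp90b1 by 0.21, hyou1 by -0.11 and the lectin chaperone canx by -1.29, which stood at 59.4 FPKM in mutant library 1 and 18.5 in mutant library 2. The list median against the wild-type mean was 0.41 in mutant library 1 and 0.27 in mutant library 2, and 2 members had no read in the latter. Without mutant library 2 the list passed with an adjusted p of 5.99e-12 and 8 genes rose adjusted over the list alone, while gut, liver and pancreas markers passed upward too (6.68e-09, with 6 genes that rose), and without mutant library 1, which leaves only the sparse library, the adjusted p was 0.0556.

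**Figure D2:**
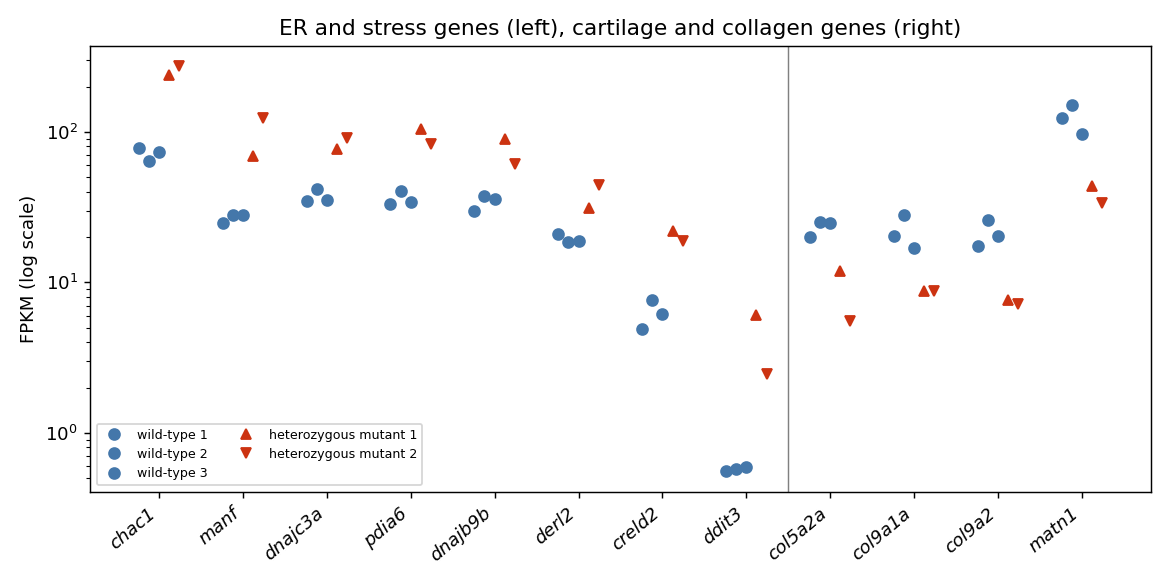
Points give the FPKM of each library on a log axis for the genes of the ER and unfolded protein response list that rose (left of the line) and the collagen and chondrocyte genes that fell (right), each adjusted over its list alone. Wild-type libraries are blue circles and mutants red triangles, and for each gene both mutants lie on 1 side of all 3 wild-type libraries, as for chac1 at 71.7 against 255 and matn1 at 124 against 38.8 FPKM on average.

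Cartilage genes and collagens were lower relative to other genes. All tested genes had a median log2 difference of -0.31, and the list medians differed from it by -0.16 for chondrocyte markers and -0.34 for collagens. The lists share the chains of type II, IX and XI collagen. Of 30 chondrocyte markers 23 were lower and 7 higher (median log2 difference -0.47), and adjusted over the list alone matn1 and col9a2 fell while 0 rose. Of 22 fibrillar and other collagens 20 were lower (median -0.65), and adjusted over the list alone 3 fell: col9a2 from 21.3 ± 4.36 (SD, n = 3) to 7.41 ± 0.398 FPKM (SD, n = 2), col9a1a from 21.8 ± 5.63 to 8.80 ± 0.0148 and col5a2a, a chain of type V collagen, from 23.4 ± 2.86 to 8.69 ± 4.43. col9a3 and hapln1b, which links aggrecan to hyaluronan, differed by -1.22 and -1.13. camera gave downward adjusted p of 0.0419 for chondrocyte markers and 0.0247 for collagens. With an estimated correlation the p were 0.225 and 0.238, with an adjusted p of 0.833 for both, and the calls were lost. In mutant library 1 the medians against the wild-type mean were -0.68 for chondrocyte markers and -0.60 for collagens, and in mutant library 2 they were -0.63 and -0.78. Without mutant library 2 both lists passed (adjusted p = 9.51e-08 and 9.95e-06), with 11 chondrocyte markers and 5 collagens that fell adjusted over the list alone, while gut, liver and pancreas markers passed upward (6.68e-09). Without mutant library 1 neither did (0.871 and 0.704), and without wild-type library 2 both stood at 0.0927.

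Bone and hypertrophy genes went both ways. Among 20 hypertrophic chondrocyte markers 12 were lower and 8 higher (camera adjusted p = 0.761). mmp13b, a collagenase of hypertrophic cartilage, stood at 2.48 ± 2.72 FPKM (SD, n = 3) in wild-type and 19.6 ± 10.3 (SD, n = 2) in mutant libraries, while alpl, the alkaline phosphatase of mineralizing cells, was at 13.4 ± 0.859 in wild-type, 9.61 in mutant library 1 and 0.0484 in mutant library 2. Among 35 osteoblast markers 27 were lower (median -0.43, camera adjusted p = 0.108, 0.00160 without mutant library 2 and 0.000413 to 0.849 over all alternatives), with sparc, a collagen-binding matrix protein, at 6866 ± 151 against 3795 ± 573 FPKM and postn, periostin, differing by -1.12. sp7, the osteoblast transcription factor, differed by -0.07, spp1 by 0.09 and phospho1, a phosphatase of mineralization, by 0.25. Adjusted over the list of 8 osteocyte markers alone, fgf23 rose and none fell, while phex, a protease that restrains it, stood at 120 ± 24.3 against 74.9 ± 3.85 FPKM (list adjusted p = 0.976, with a median of -0.44 and an upward camera direction). Among 8 osteoclast and bone resorption genes 4 were higher and 4 lower (0.649). The collagen synthesis and secretion machinery, 30 genes, did not pass (0.716), with 19 lower, a median of -0.25 and an upward camera direction. Its members p4ha1b, a prolyl hydroxylase, and ppib, a prolyl isomerase, differed by 0.92 and 0.71. Matrix proteases and their inhibitors, 40 genes, had an adjusted p of 0.522, with medians of -0.27 in mutant library 1 and -0.79 in mutant library 2.

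Ribosomal protein genes showed the most uniform difference of the lists tested. Of 63 genes 61 were higher in the mutants, with a median log2 difference of 0.997, and 50 rose adjusted over the list alone, although 0 passed over all genes. rpl39 stood at 65.8 ± 32.5 FPKM (SD, n = 3) against 207 ± 49.8 (SD, n = 2), rpl35a at 120 ± 32.8 against 285 ± 22.9 and rps25 at 53.2 ± 14.3 against 123 ± 22.0. Nuclear genes of oxidative phosphorylation were also higher, 40 of 52 with a median of 0.50 and 0 passing adjusted over the list alone. cox7c, a cytochrome c oxidase subunit, differed by 1.16 and atp5f1e, an ATP synthase subunit, by 1.37. camera gave upward adjusted p of 1.99e-46 and 1.13e-12. With an estimated correlation the p were 0.0772 and 0.168, with an adjusted p of 0.833 for both, so the calls were lost. The ribosomal median differed between wild-type libraries as well, at 0.40, -0.11 and -0.27 against their mean, and was 0.88 and 1.14 in mutant libraries 1 and 2. The oxidative phosphorylation medians were 0.29, -0.18 and -0.11 in the wild-type and 0.57 and 0.42 in the mutant libraries. Mitochondrial genes took 5.48%, 4.07% and 3.74% of reads in the wild-type and 7.09% and 4.80% in the mutant libraries.

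Genes of BMP and TGF-beta signalling and of glycolysis were lower relative to other genes. Against the median of all tested genes, -0.31, their medians differed by -0.22 and -0.26. Of 42 genes of BMP and TGF-beta signalling 37 were lower (median -0.53), among them the ligands bmp8a at 156 ± 32.2 FPKM (SD, n = 3) against 76.8 ± 13.7 (SD, n = 2) and bmp4 at 89.2 ± 14.5 against 43.7 ± 26.6. Of 28 glycolysis genes 26 were lower (median -0.57), including the aldolase aldoa at 42.6 ± 4.56 against 22.4 ± 16.4 FPKM and the enolase eno1a at 57.8 ± 8.58 against 36.0 ± 13.0. camera gave a downward adjusted p of 0.0247 for each, which an estimated correlation ended, with p of 0.236 and 0.415 and adjusted p of 0.833 and 0.849. No member of either list passed adjusted over the list alone. The BMP and TGF-beta median was -0.38 in mutant library 1 and -0.73 in mutant library 2, with an adjusted p of 0.000394 without the latter, the lowest of all alternatives, 0.520 without mutant library 1 and 0.0595 without wild-type library 3. The glycolysis median was -0.21 in mutant library 1 and -1.002 in mutant library 2, and the list no longer passed without mutant library 2 (0.514, in a range from 0.00229 to 0.849). Of 28 primary cilium genes 16 were higher (median 0.09, camera adjusted p = 0.0255, and with an estimated correlation p = 0.151 and adjusted p = 0.833), but TMEM216, at 22.6 ± 1.48 against 50.4 ± 16.9 FPKM, was the only member with an unadjusted p under 0.05 and 0 passed adjusted over the list alone. That median was -0.17 in mutant library 1 and 0.24 in mutant library 2. The cilium list lost its call without mutant library 2 (0.676) and without wild-type library 1 (0.0557), and its median turned to -0.06 with no filter on low values (adjusted p 0.00762 to 0.833 over all alternatives). Wnt signalling, 42 genes of which 34 were lower, had an adjusted p of 0.0785, 9.95e-06 without mutant library 2 and up to 0.833 in other alternatives. The receptor fzd2 stood at 60.8 ± 8.94 against 25.8 ± 15.6 FPKM. Hedgehog signalling had an adjusted p of 0.279, with medians of -0.29 in mutant library 1 and -1.01 in mutant library 2.

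**Figure D3:**
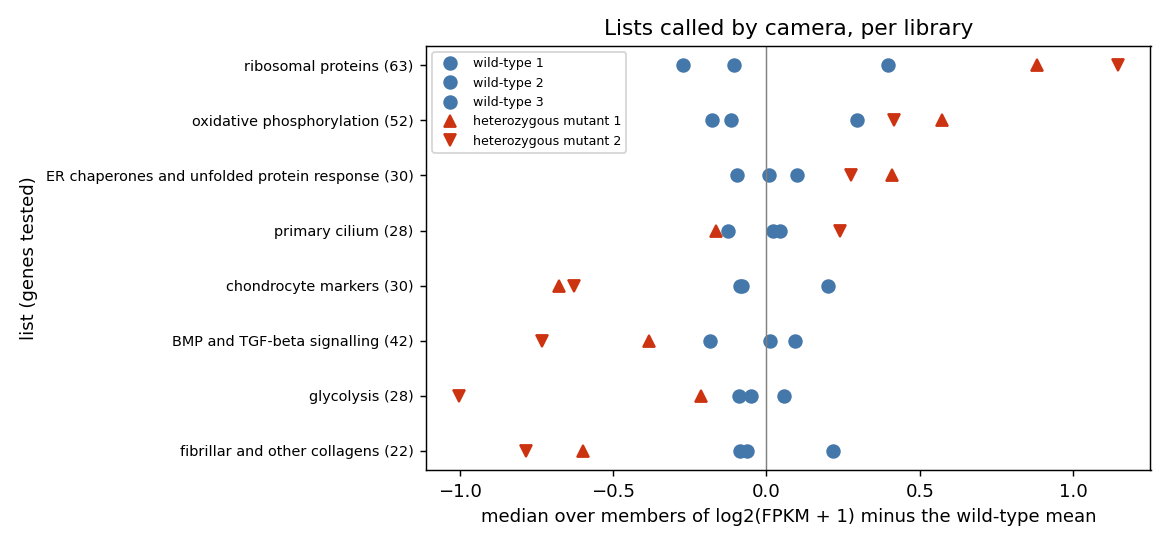
For each list that passed camera with the preset correlation, points give the median over its members of log2(FPKM + 1) minus the wild-type mean, per library, with wild-type in blue and mutants in red and the number of genes tested in brackets. Ribosomal protein medians reach 0.88 and 1.14 in the mutants and chondrocyte medians -0.68 and -0.63, whereas the primary cilium medians, -0.17 and 0.24, lie on opposite sides of 0.

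The remaining functional lists did not pass camera. Genes of cell polarity, 35 tested, had an adjusted p of 0.649 (0.0389 and downward with a minimum of 5 FPKM), and its members with the smallest p, prickle1a, pard6a, prkci and prickle3, differed by -1.25 to -2.03 and stood at 0, 0, 2.86 and 0.494 FPKM in mutant library 2. Adjusted p were 0.761 for microtubule and centrosome organisation, 0.200 for the actin cytoskeleton and focal adhesion, 0.214 for cell junctions and cadherins, 0.761 for apoptosis, 0.214 for the cell cycle (0.0228 and downward without mutant library 2, up to 0.849 elsewhere), 0.0869 for the proteasome and autophagy (0.0114 and upward without wild-type library 3) and 0.522 for cholesterol synthesis (0.0432 and downward without wild-type library 3). Medians in mutant libraries 1 and 2 were -0.19 and -0.68 for actin and adhesion genes, -0.32 and -1.08 for junction genes, -0.32 and -0.70 for the cell cycle and -0.12 and -0.95 for cholesterol synthesis. dhcr7, an enzyme of sterol synthesis, stood at 47.1 ± 2.44 (SD, n = 3) against 18.4 ± 14.6 FPKM (SD, n = 2). For immediate early and heat shock genes, whose levels also follow tissue handling, the adjusted p was 0.649 (0.0135 and downward without mutant library 2, up to 0.925 elsewhere). In that list atf3, a stress-induced transcription factor, stood at 9.56 ± 4.24 against 28.8 ± 4.94 FPKM, while jun and dusp1 differed by -0.66 and -0.86. For microtubule genes, apoptosis, the proteasome, immune and endothelial markers the median was below 0 and the camera direction upward.

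Markers of other cell types did not pass camera either. Adjusted p were 0.320 for skeletal muscle (0.0431 and downward at a mean of at least 20 FPKM), 0.368 for epidermis, 0.761 for immune cells, 0.221 for neural and glial cells, 0.761 for endothelium, 0.761 for pigment cells, 0.170 for fibroblasts and tendon (0.0403 and downward without mutant library 2, up to 0.833 elsewhere), 0.522 for notochord, 0.640 for retina, lens and inner ear and 0.649 for gut, liver and pancreas. Blood markers had fewer than 5 tested members. Muscle transcripts were abundant in all groups, with the skeletal actin acta1 at 610 ± 97.6 FPKM (SD, n = 3) in wild-type and 356 ± 209 (SD, n = 2) in mutant libraries. Liver transcripts were too. The apolipoprotein gene apoa1b took 6.81%, 5.25% and 5.54% of reads in wild-type and 8.61% and 3.34% in mutant libraries, and fabp10a, a liver fatty acid-binding protein, stood at 5686 ± 1163 against 11189 ± 3615 FPKM. Adjusted over the list of 22 gut, liver and pancreas genes alone, ins rose and 0 fell. The median of this list was 0.49 in mutant library 1 and -0.89 in mutant library 2, below 0 overall (-0.47) where the camera direction was upward. Without mutant library 2 the list passed upward with an adjusted p of 6.68e-09 (up to 0.956 in other alternatives), and 6 genes rose adjusted over the list alone. Epidermal, neural and endothelial medians were -0.16, -0.11 and -0.15 in mutant library 1 and -1.21, -1.38 and -1.18 in mutant library 2. Pigment and retina medians were -0.02 and 0.04 in mutant library 1 and -1.46 and -1.11 in mutant library 2.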

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

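Added after the data were seen were the tests with voom quality weights, the length trend removed, a mean of at least 20 FPKM and the members called within each list alone without mutant library 2. The ADP-ribosylation factor gene passed in every setting (log2 8.34 to 9.10, highest adjusted p 0.0256). Genes passing numbered 145 with the replicate block (22 higher, 123 lower), 2 with voom on recovered reads and 1 to 7239 with each library left out, 7239 without mutant 1 and 2 without mutant 2. All other settings gave 1, and a threshold of 0.1 also gave 1. The labels do not say that replicate numbers pair samples. The correlation of deviations was 0.06 for number 1 and -0.01 for number 2. With 2 mutants, their deviations from the group mean are exact opposites, so this check can neither show nor exclude pairing. The block leaves 1 residual degree of freedom among samples, since wild-type 3 has a number of its own. Lists passing numbered 5 with array weights, which weighted the mutants at 0.279 each, 0 with an estimated correlation, 0 by fry and 4 to 12 with each library left out. col10a1a ran from -0.78 to -0.56 with each library left out, and passed without mutant 1. Among named genes 1690 of 1709 values outside leave-one-out kept direction and side of the threshold, 19 newly passed and 0 reversed. For all named genes but the ADP-ribosylation factor gene, keeping the side means not passing. Most were picked for a small p in these same libraries, so the count is no test of their differences. With a library left out the sign turned for col10a1b (-0.68 to 0.26), acp5a (-0.63 to 2.11), clcn7 (-0.10 to 0.89) and pmela (-3.14 to 0.16). ins fell below the filter without mutant 1 and without mutant 2 and has no value in either. Of 474 list values outside leave-one-out 410 kept direction and side, 28 lost the call, 12 gained it and 24 reversed. The gains included cholesterol (0.000947), proteasome (0.0154) and neural genes (0.0466) with the block. With an estimated correlation the adjusted p of called lists was 0.833, and 0.849 for glycolysis. fry gave 0.116 for ER genes and BMP signalling, 0.0944 for collagens and chondrocyte markers, 0.597 for cilium, 0.234 for glycolysis and oxidative phosphorylation and 0.118 for ribosomal proteins. Array weights gave 0.0677 for collagens, chondrocyte markers and BMP signalling. The 2 mutants deviate equally from their mean, so their array weights are equal and cannot single out the sparse library. Chondrocyte markers had 0.0588 with no filter, 0.0696 with no trend, 0.0864 with voom, 0.0908 with quality weights and 0.0516 at a mean of at least 20 FPKM, BMP signalling 0.0516 there and 0.202 with the block, cilium 0.197 with no filter and glycolysis 0.0551 with no trend. With each library left out the called lists ran as follows: ER genes 5.99e-12 to 0.0556, collagens 9.95e-06 to 0.704, chondrocyte markers 9.51e-08 to 0.871, cilium 0.0116 to 0.676, BMP signalling 0.000394 to 0.520 and glycolysis 0.0129 to 0.514. Lists that had not passed turned direction as follows, by adjusted p. Collagen machinery 0.595 (quantile), 0.403 (fry). Osteocyte 0.995 (pseudocount 0.1), 0.998 (no filter), 0.646 (5 FPKM), 0.544 (quantile), 0.944 (array weights), 0.917 (replicate block), 0.797 (voom), 0.562 (fry). Osteoclast 0.998 (no filter), 0.807 (fry). Apoptosis 0.652 (quantile), 0.546 (mean of 20 FPKM), 0.176 (fry). Immune 0.678 (no filter), 0.385 (fry). Gut, liver and pancreas 0.544 (quantile), 0.249 (replicate block), 0.949 (quality weights), 0.349 (mean of 20 FPKM). By fry also microtubule 0.0944, proteasome 0.832 and endothelial 0.267. With a library left out, turned lists ran from 0.429 to 0.817 for collagen machinery, 0.309 to 0.937 hypertrophic, 0.817 to 0.993 osteocyte, 0.423 to 0.954 osteoclast, 0.809 to 0.908 microtubule, 0.0432 to 0.973 cholesterol, 0.0135 to 0.833 immediate early, 0.0556 to 0.473 neural, 0.516 to 0.880 pigment, 0.109 to 0.937 notochord, 0.436 to 0.767 retina and 6.68e-09 to 0.880 gut. Leaving out a library leaves fewer samples, and for the other shifts the cause was not tested. Depth limits genes under 3 reads, 0.0871 to 0.120 FPKM at 1 kb. Depth does not account for the 374 genes without a read in mutant library 2, which had 27916294 reads.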

Other observations

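The gene lists introduced in this part and the tests of near copies, gene length, islet and pancreas genes were chosen after the results had been seen, while leaving out a library and estimating the correlation for the ER list were fixed in advance. Among genes of protein entry into the ER, the members seen first, ssr2, ssr3, ssr4, sec61b, krtcap2 and the 2 genes named dad1, had a median log2 difference of 1.15, and all 7 rose adjusted over the list alone, as genes picked for being high would. Of 22 further genes of the translocon, signal recognition and oligosaccharyltransferase 16 were higher, with a median of 0.33 and 0 passing adjusted over the list alone (with an estimated correlation p = 0.0156, and 0.101 without mutant library 2). Among them were spcs2 and sec11a, subunits of the signal peptidase, with log2 differences of 0.80 and 0.77, SEC61A1, the channel itself, with 0.74, and srp19, of the signal recognition particle, with 0.77. The paralogous catalytic subunits stt3a and stt3b differed by 0.36 and -0.69, and tusc3, with no read in mutant library 2, by -1.46. Genes of vesicle coats between ER and Golgi were higher too, 26 of 36 with a median of 0.53 (camera p = 1.29e-09, and with an estimated correlation p = 0.0679) and 0 passing adjusted over the list alone. Without mutant library 2 their median was 0.21, with p = 0.130 at an estimated correlation. The cargo receptors tmed9 and tmed10 differed by 0.73 and 0.82.

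Exocrine pancreas genes separated the mutant libraries. Of 15 tested, 14 were higher in mutant library 1 than in the wild-type mean, with a median of 1.30. That rise describes 1 library only, so it has no spread among mutants behind it. In mutant library 2 the median was -4.15 and 11 of the 15 had no read.

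The gene described as ADP-ribosylation factor 4 was 8.79 log2 units higher in the mutants and stood at 12.2 FPKM or less in the wild-type libraries. Reads taken from the 9 other tested genes described as ADP-ribosylation factors do not account for it. They lost 0.375% of what it gained in depth-scaled reads, and arf5 and ARF5 were themselves higher. Copies that are described otherwise or were not tested, and reads assigned to no gene in the wild-type libraries, were not covered. Other mapping causes therefore stay open. The sparse library does not account for it either, since the log2 difference was 8.70 without mutant library 2. The gene is on chromosome 5, and the copies of col10a1 are on chromosomes 22 and 24. A sequence variant near the gene and the genotype itself stay open, as untested.

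The rise of ER genes relative to other genes does not rest on the sparse library alone. Without mutant library 2 the list median was 0.39, where that of all tested genes was -0.16. Without mutant library 1 the 2 medians were 0.27 and -0.47. Each of these settings leaves 1 mutant library, so neither shows how far the rise would recur among mutants. Gene length does not account for it, since length predicted a shift of -0.0411 where 0.60 was observed. The translocon and oligosaccharyltransferase genes not seen first gave an upward camera p of 3.05e-06 (with an estimated correlation p = 0.0156, and 0.101 without mutant library 2). The estimated correlation gave the ER list itself p = 0.0314 and an adjusted p of 0.833. The genotype itself and a difference in cell composition between the groups stay open. In mutant library 1 gut, liver and pancreas markers had a median of 0.49 and exocrine genes of 1.30, beside 0.41 for ER genes. In mutant library 2 these medians were -0.89, -4.15 and 0.27, so such markers went with the ER genes in mutant library 1 only.

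Insulin transcripts were higher in both mutants, and a second gene described as insulin (ENSORLG00000023683, chromosome 14, 5935119 to 5936842) stood at 0.110, 0.0973 and 0.258 FPKM in wild-type and 2.04 and 9.01 in mutant libraries. Islet cells carried into the mutant libraries could raise ins, and other islet genes then should be higher, but their median was 0.0165 without mutant library 2, against 3.0002 for ins in mutant library 1. With both mutants 2 of 14 were higher and the median was -0.86. Those were GCG and pyyb, at 43.8 and 8.72 FPKM in mutant library 2 against at most 23.4 and 3.74 in wild-type libraries. Others, such as scg2b and neurod1, had no read in mutant library 2. The wild-type median of these islet genes, 4.73 FPKM, could hide a small share, so this cannot be told apart. Carried-over pancreas tissue would raise exocrine genes, as in mutant library 1 (median 1.30), but in mutant library 2 the median was -4.15. There 11 of 15 exocrine genes had no read, against 27 of 2376 genes at 20 FPKM or more in all 4 other libraries. Some of the 15 lay below 20 FPKM there, so the shares are not alike. Of those that reached it, zgc:112160, ctrb1, ctrl, cpb1 and CELA1 (ENSORLG00000006967) had no read in mutant library 2. tryp, prss1 and CELA1 (ENSORLG00000006922) kept reads. prss1, which kept reads, stood at 205, 262 and 190 FPKM in wild-type libraries and 11.3 in mutant library 2, where ins was at 10.3. For that 1 library these values argue against whole pancreas tissue as the source of ins. In mutant library 1 prss1 stood at 537 FPKM and ins at 9.80, where wild-type libraries had ins at 0.315 to 0.369. There carried-over tissue stays open only if it held more ins per exocrine transcript than the wild-type libraries did.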
